A study of Mus musculus with 6 samples.

How the data were processed

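Gene expression was measured on 6 one-colour microarrays of mouse T cell leukemias, 3 from wild-type donor marrow and 3 from marrow of Sh2b3 knockout donors. Per the labels' protocols, lineage-depleted marrow progenitors were infected with a retrovirus carrying an activated form of NOTCH1 that lacks the extracellular part, and were transplanted into irradiated C57BL6 recipients. Leukemia was followed in blood by the green fluorescent reporter and by CD4 and CD8. RNA was extracted from the tumours with a column kit for small samples, amplified with a whole-transcriptome kit for picogram inputs, and labelled with biotin, per the labels' protocols. Amplification of small inputs can compress or distort differences between transcripts.

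The deposited values are on a log2 scale, with 45101 probe sets per array and 2 decimals. GCRMA, which corrects background by probe sequence, normalizes between arrays and summarises probes, is the only tool named per the submitters' processing notes; its version and settings are not given in the sources used here. That the base of the logarithm is 2 was taken from the range of the values. The array medians lay between 2.26 and 2.36, and the highest values between 14.68 and 14.76. Low GCRMA values lie close together, so that differences near 2 on this scale carry little information. The 6 arrays were used as deposited, with no further normalization. Their number limits the precision.

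Probe sets were named through the platform annotation, with symbols updated through gene identifiers to a RefSeq gene table of the mouse assembly GRCm38.p6. That table was used for names, chromosomes and the order of genes only. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none; these include 64 control probe sets. Only probe sets with 1 symbol were used. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays, and 12564 genes with a mean above the 40th percentile of all probe set means, 2.04, were tested.

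Knockout minus wild type was tested with limma (version 3.58.1 in R 4.3.3), by lmFit and eBayes with an intensity trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors printed beside log2 fold changes are the moderated ones of this fit. The probe sets of Sh2b3 also had a two-sided exact permutation test, which with 3 against 3 cannot give a p below 0.1. Gene lists, 29 in all, were fixed before the data were examined. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. List members were also adjusted over the list alone.

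Genes named in the text follow a rule fixed before the data were examined. It takes every probe set of Sh2b3; the 12 genes per direction with the smallest p and an absolute log2 fold change of at least 1, filled with genes that miss the threshold; and from each list the members past the threshold, or else up to 4 with the smallest p. For the lists of neighbours of Sh2b3 and of sex-linked genes any member may be named. In the text 1 predicted gene, lower in knockout, was skipped. Genes named outside this rule are said to have been chosen after their values were seen.

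The test was checked on simulated arrays with 12564 genes, 200 of them changed, over 20 simulations. It recovered 36.1% of genes changed by 1 on the log2 scale, 88.6% at 2, 96.5% at 3 and 99% at 4, with a mean of 8.45 false calls. The simulated genes varied independently of each other, so that the simulated lists say nothing about correlated genes. The simulated arrays were also independent, with no near-identical pair such as wild-type replicates 1 and 2. The recovery rates therefore need not hold for these data, where Sh2b3 itself, at -2.11, missed the threshold.

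The labels call the samples biological replicates and also say that RNA was isolated in triplicate, without tying arrays to animals. The p-values measure the spread between these arrays, which may in part be technical. Alternatives were the low value filter, the prior variance, the normalization, array weights, the replicate number as a block, each array left out, the mean over probe sets, all probe sets, the thresholds and the list test. After the data were seen, a fit with wild-type replicates 1 and 2 averaged was added. An alternative pseudocount was not run, because the values are already logarithms.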

Results

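The data compared T cell leukemias induced by activated NOTCH1 in mice, 3 arrays from wild-type donor marrow and 3 from Sh2b3 knockout donor marrow. Sh2b3 encodes LNK, an adaptor protein that restrains signalling from cytokine receptors and JAK kinases. The comparison addresses which transcripts differ between leukemias with and without this adaptor. Values are log2 signals as mean ± SD with n = 3 per group, and log2 fold changes are knockout minus wild type.

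The Sh2b3 transcript was lower in every knockout array than in every wild-type array. Its more intense probe set read 4.39 ± 0.39 in wild type and 2.27 ± 0.03 in knockout (SD, n = 3), a log2 fold change of -2.11 with a standard error of 0.247. The knockout values lie near the bottom of the scale. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows, and the adjusted p from limma was 0.158. The other probe set read 1.85 ± 0.11 in wild type and 1.82 ± 0.02 in knockout, near the bottom of the scale in both groups, and checks nothing. The labels do not say which exons are deleted. Without wild-type replicate 3 the Sh2b3 log2 fold change was -2.27 with an adjusted p of 0.0206, in a range of 0.0206 to 0.765 over 16 alternatives; with the mean of both probe sets it was -1.07.

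No gene passed the threshold over all genes. With limma, 0 genes were higher and 0 lower in knockout among 12564 tested, with a lowest adjusted p of 0.158. At an unadjusted p under 0.05 there were 981 genes, 416 higher and 565 lower, where 628 are expected by chance. The groups did not overlap for 1733 genes, 13.8% against the 10% that chance gives for 3 against 3 independent arrays. Both chance values take all arrays as independent, which the near-identical pair of wild-type arrays described below puts in doubt. Other splits of the samples that kept this pair together gave 871, 895 and 973 genes at an unadjusted p under 0.05. The excess over either chance value therefore cannot be read as a difference between knockout and wild type. Without wild-type replicate 3 the genes past the threshold became 20 higher and 31 lower. Without knockout replicate 1 they were 3 higher and 0 lower, and without knockout replicate 3 they were 1 higher and 0 lower.

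The arrays of wild-type replicates 1 and 2 were far closer to each other than any other 2 arrays. Over 6724 genes with a mean above 5, the SD of their difference was 0.234, against 0.503 to 0.689 for the other 14 pairs. Of these genes, 10 differed by more than 1 between these 2 arrays, against 298 to 666 in the other pairs. Both were kept as samples, and averaging them into 1 sample gave 0 genes higher and 0 lower, 502 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.440. The low spread within this pair is what remains of the wild-type group without wild-type replicate 3.

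**Figure D1:**
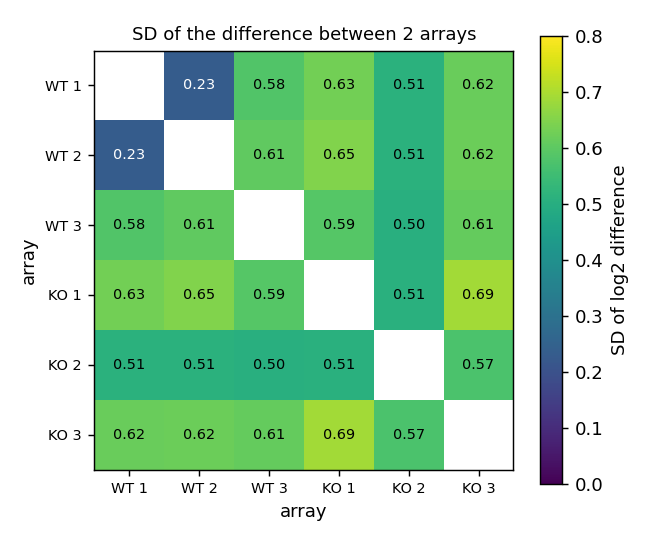
Heat map of the SD, over tested genes with a mean above 5, of the log2 difference between each 2 of the 6 arrays (WT, wild type; KO, knockout). The pair of wild-type replicates 1 and 2 reads 0.23, and the other pairs read 0.50 to 0.69.

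Ddc, the enzyme that makes dopamine and serotonin from their amino acid precursors, had the smallest p of all genes, at 6.04 ± 0.64 in wild type and 2.70 ± 0.24 in knockout, a log2 fold change of -3.34 (standard error 0.360, adjusted p = 0.158 by limma). Naip5, Naip6 and Naip2, sensors of bacterial proteins in inflammasomes, had log2 fold changes of -3.70, -2.06 and -1.79. Eid2 stood at -2.64, Pik3r3, a regulatory subunit of phosphoinositide 3-kinase, at -2.44, and the G protein subunit gene Gnb4 at -1.39. The noncoding RNA genes Dancr and Snhg4 had -1.50 and -1.02, and Ext2, needed to build heparan sulfate, had -1.09. None of these passed the threshold, with adjusted p between 0.158 and 0.418. For each of them the 3 knockout values lay below the 3 wild-type values. Their selection by the smallest p favours this, and the groups did not overlap for 1733 of the 12564 genes tested. Naip2, Naip5 and Naip6 are close relatives whose probes can share sequence. Knockout values of Ddc, Naip6 and Naip2, and of Naip5 on knockout array 2, lie near the bottom of the scale, so the sizes of these differences are uncertain.

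Among genes with higher values in knockout, B3gnt5, a glycosyltransferase of glycolipid synthesis, went from 3.70 ± 0.91 to 6.87 ± 0.23, a log2 fold change of 3.17 (standard error 0.441, adjusted p = 0.221 by limma). Pmaip1, which encodes the proapoptotic protein NOXA, had a log2 fold change of 3.01, and Tut4, which adds uridines to RNA, had 2.53. Fos, a component of the AP-1 transcription factor, read 2.71 ± 0.28 in wild type and 5.01 ± 0.49 in knockout. Erdr1 had 2.32, the protease inhibitor gene Slpi 2.23, and Pou2af1, a transcriptional coactivator of B lymphocytes, 2.22. Serf1 had 1.93, Mcoln2 1.77, Hspa4l 1.71, Gimap4 1.63 and the DNA sensor gene Cgas 1.18. Adjusted p for these 12 genes ranged from 0.221 to 0.628. Again the groups did not overlap for any of them, which their selection by p favours. Erdr1 read 9.21 on knockout array 1 and 11.62 and 11.59 on the others; without knockout replicate 1 its log2 fold change was 3.12 and passed the threshold (adjusted p = 0.00190, in a range of 0.00190 to 0.984 over its alternatives). Without wild-type replicate 3, which leaves the near-identical arrays 1 and 2 as the wild type, Ddc, Gnb4, Naip2, Naip6, B3gnt5, Hspa4l, Pmaip1, Pou2af1, Tut4, Dtx1, Gzma and Jchain passed, with adjusted p between 0.00697 and 0.0387. Over all alternatives adjusted p for these genes ranged from 0.00697 to 0.984, and Ddc also passed with array weights (0.0210). The less intense probe sets of Serf1 had log2 fold changes of 0.71 and 0.36, with no overlap between groups, and -0.19, with wild-type values near the bottom of the scale. Fos in wild type also lies there, so the size of its difference is uncertain. On wild-type arrays 1 and 2, Pmaip1 read 2.78 and 3.45 and B3gnt5 3.4 and 2.98, low on the scale. The sizes of their differences are uncertain too.

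**Figure D2:**
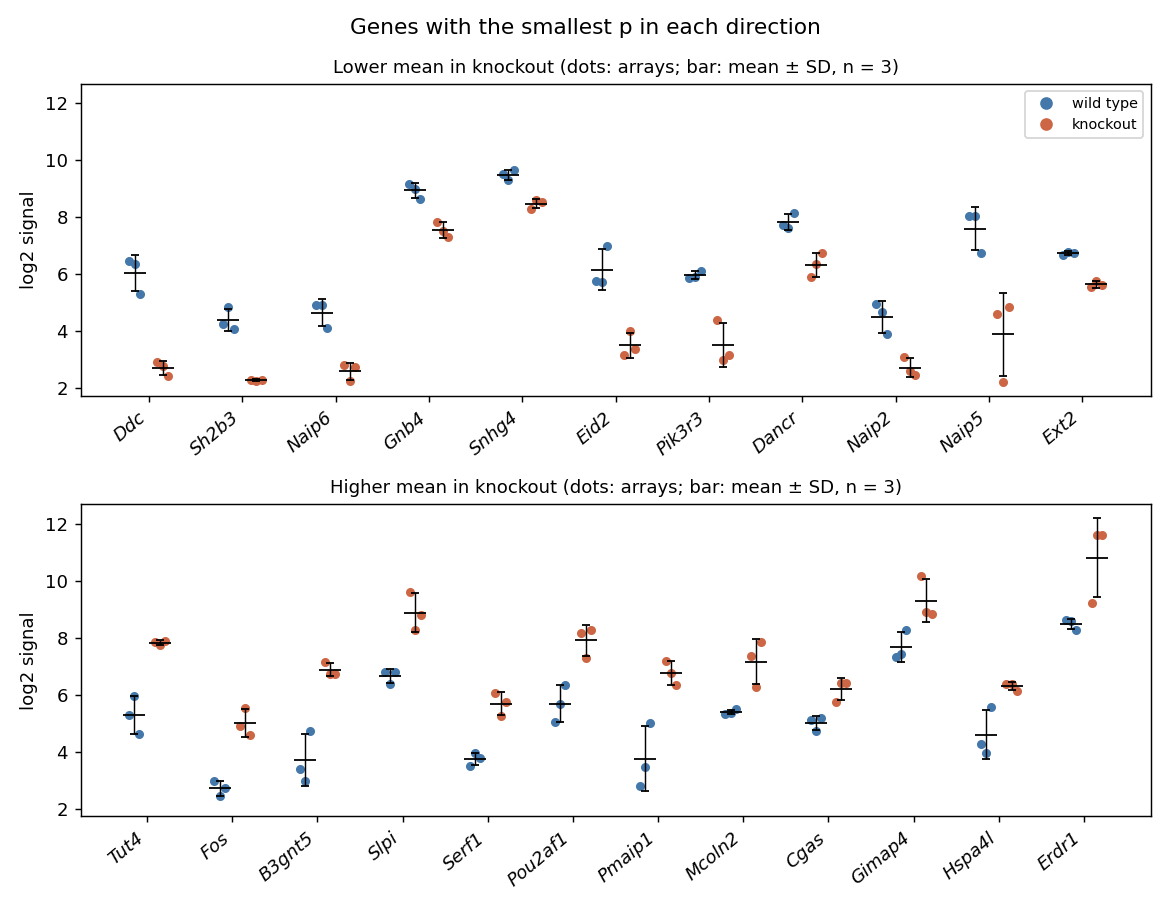
Log2 signal on each array for the genes with the smallest p and an absolute log2 fold change of at least 1, by direction; blue dots are wild type, orange dots are knockout, and bars give the mean ± SD of 3 arrays. Knockout and wild-type values do not overlap for any gene shown, which the selection by p favours, and Naip5 in knockout has the widest spread, an SD of 1.46.

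Of the 29 gene lists, 6 passed the threshold with camera at the preset correlation. They did not hold with an estimated correlation, where 0 lists passed, nor with fry's directional test, where 0 passed. For each of the 6, the mean over members on knockout array 3 lay inside the range of the wild-type arrays or, for MYC and ribosome biogenesis genes, at its upper end. Other splits of the 6 samples gave up to 15 lists past the threshold.

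Dendritic cell and MHC class II genes, which present antigen to T cells, stood higher in knockout in 7 of 8 tested members, with a median log2 fold change of 0.75 and an adjusted p of 0.00151 (adjusted p = 0.826 with an estimated correlation). H2-Ab1 had a log2 fold change of 0.61, Irf8 0.79, Batf3 0.75 and Ciita, the activator of MHC class II transcription, 0.41. No member passed the threshold over all genes, and 0 passed when adjusted over the list alone. The mean over members relative to wild type was 0.83 and 0.92 on knockout arrays 1 and 2 and 0.03 on knockout array 3, against -0.12 to 0.10 on wild-type arrays. B lymphocytes also express MHC class II genes, and the list of B cell markers had means, relative to wild type, of 0.53, 0.55 and -0.22 on knockout arrays 1, 2 and 3; its members Blnk and Cd79b read 5.19 and 7.34 on knockout array 2 and 3.45 and 4.74 on knockout array 3. Batf3 and Ciita lie near the bottom of the scale in both groups. The call was kept in 16 of 16 alternatives that refit the genes.

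Interferon-stimulated genes stood higher in 15 of 17 members, with a median of 0.34 and an adjusted p of 0.00174 (adjusted p = 0.826 with an estimated correlation). Ifih1, a sensor of viral RNA, had 1.41, Rtp4 1.54, Gbp2 1.07 and Rsad2 1.06; 0 members passed over all genes and 0 adjusted over the list alone. The list mean was 1.16, 0.42 and -0.10 on the 3 knockout arrays. Without knockout replicate 1 the adjusted p was 0.244, in a range of 8.87e-07 to 0.244 over 16 alternatives.

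Plasma cell genes stood higher in 4 of 6 members, with a median of 0.52 and an adjusted p of 0.0455 (adjusted p = 0.826 with an estimated correlation). Mzb1 had 2.28, Jchain, the joining chain of secreted immunoglobulins, 1.68, Xbp1 0.49 and Derl3 0.56. Over all genes 0 members passed, and 3, Xbp1, Mzb1 and Jchain, passed when adjusted over the list alone. Jchain read 10.68 on wild-type array 3, close to the knockout values, and 8.42 and 8.72 on wild-type arrays 1 and 2. Without knockout replicate 2 the adjusted p of the list was 0.309, in a range of 0.00793 to 0.309. The call was also lost with the mean of probe sets (0.0701), a constant prior variance (0.0566) and the replicate block (0.0553).

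ERK feedback and immediate early genes went both ways, with 12 of 20 members higher, a median of 0.17 and an adjusted p of 0.0472 (adjusted p = 0.826 with an estimated correlation). Fos passed when adjusted over the list alone, 1 of 20 members, and 0 passed over all genes. Egr3 had 1.97 and Dusp1 1.12, whereas Dusp6, which inactivates ERK, had -1.47. Egr3 read 1.62 to 2.04 in wild type and 2.01 on knockout array 3, at the bottom of the scale, so the size of its difference is uncertain; without knockout replicate 3 it passed the threshold over all genes (adjusted p = 0.0453, in a range of 0.0453 to 0.984 over its alternatives). The call of the list was lost without wild-type replicate 1 (adjusted p = 0.152), wild-type replicate 2 (0.105), knockout replicate 1 (0.358) and knockout replicate 2 (0.187). It was also lost with wild-type replicates 1 and 2 averaged (0.129), no low value filter (0.106), a constant prior variance (0.0566) and the replicate block (0.0553), in a range of 0.000374 to 0.358.

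Glycolysis genes stood lower in 11 of 14 members, with a median of -0.22 and an adjusted p of 0.0472 (adjusted p = 0.826 with an estimated correlation). Pkm had -0.69, Aldoa -0.46, Pdk1 -0.42 and Pgam1 -0.31. MYC and ribosome biogenesis genes stood lower in 17 of 20 members, with a median of -0.17 and the same adjusted p by camera (0.826 with an estimated correlation). Ddx21 had -0.49, Polr1b -0.78, Fbl -0.26 and Nolc1 -0.42. In both lists 0 members passed over all genes and 0 adjusted over the list alone. Glycolysis lost its call without wild-type replicate 3 (adjusted p = 0.330), knockout replicate 1 (0.358) and knockout replicate 2 (0.139), and with array weights (0.131), a constant prior variance (0.109) and the filter at the 60th percentile (0.0712), in a range of 0.000722 to 0.358. The MYC list lost its call without the same arrays (0.463, 0.632 and 0.354) and settings (0.0698, 0.110 and 0.151), and with the mean of probe sets (0.0722), in a range of 2.45e-07 to 0.632.

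**Figure D3:**
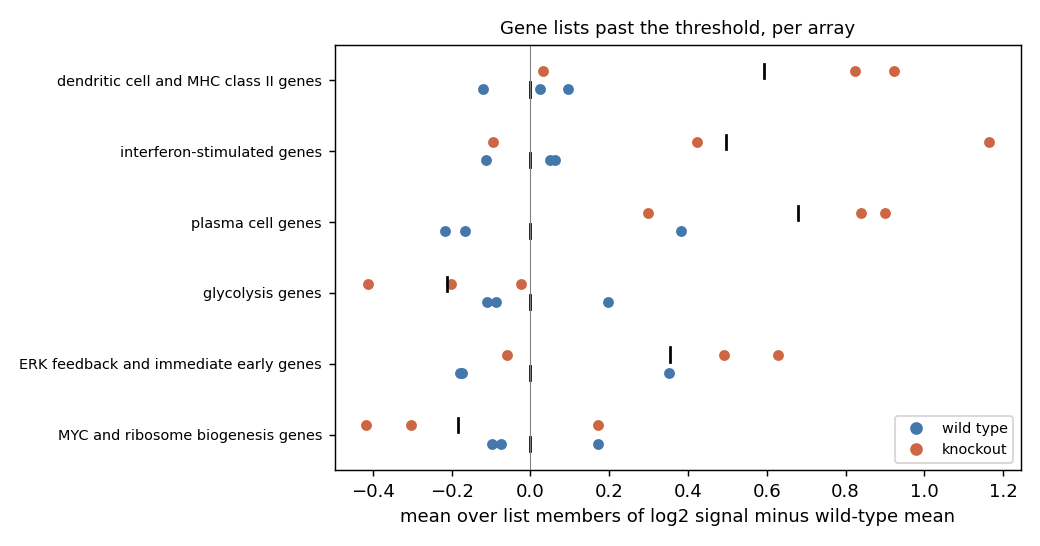
Mean over list members of the log2 signal minus the wild-type mean, for the 6 lists past the threshold with camera at the preset correlation; each dot is an array and short bars mark group means. Dots of knockout array 3 lie among or beside the wild-type dots, as at 0.03 for MHC class II genes and -0.10 for interferon-stimulated genes.

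Cytokine signalling, which the missing adaptor restrains, showed no list past the threshold. STAT5 and cytokine response targets had 6 members higher and 8 lower (camera adjusted p = 0.674). Socs3, a feedback inhibitor of cytokine receptors, had a log2 fold change of -0.89 and Bcl6 -1.08. Cish, Socs2, Osm, Lta and Gzmb, chosen after their values were seen, had group means of 2 to 3.25. These lie near the bottom of the scale, where a change could be missed. Cytokine receptors, JAK kinases and STATs had 7 higher and 13 lower or with equal means (adjusted p = 0.614). Il7r, the interleukin 7 receptor, read 6.37 ± 0.44 in wild type and 7.86 ± 1.86 in knockout, with a standard error of the difference of 0.792, from 9.96 on knockout array 3 and 6.43 to 7.20 on the other knockout arrays, against 6.10 to 6.87 in wild type. Jak1 had -0.49. Negative regulators and adaptors had 5 higher and 14 lower (adjusted p = 0.522), with Ptpn11 at -0.41 and Ptpn2 at 0.24. In each of these 3 lists 0 members passed, over all genes or adjusted over the list alone.

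NOTCH1 targets had 6 members higher and 9 lower (adjusted p = 0.614). Notch3 had -0.57, Dtx1 -0.63 and Notch1 -0.35. Dtx1 lies on chromosome 5, in the gene window around Sh2b3. Without wild-type replicate 3 the list was called lower (adjusted p = 0.0368), in a range of 0.0368 to 0.960 at the preset correlation; on all 6 arrays the adjusted p was 0.826 with an estimated correlation. T cell receptor and mature T cell genes had 5 higher and 13 lower (adjusted p = 0.522), with Cd2 at 0.45 and Cd8a at -0.53; it was called lower without wild-type replicate 3 (adjusted p = 0.0198) and without knockout replicate 1 (0.0459) and turned to higher without knockout replicate 3 (0.155), in a range of 0.0198 to 0.960, and on all 6 arrays had an adjusted p of 0.826 with an estimated correlation. Early thymocyte genes had 6 higher and 9 lower (adjusted p = 0.741); the median was -0.10 and the mean 0.07, with Bcl11b at -0.55 and Mycn at -0.85. Stem and progenitor genes had 7 higher and 4 lower (adjusted p = 0.537). T-ALL tumour suppressors had 6 higher and 8 lower (adjusted p = 0.568), with Fbxw7, which targets activated NOTCH1 for degradation, at -0.68. No member of these 5 lists passed, over all genes or adjusted over the list alone.

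Of the p53 targets 5 were higher and 10 lower (adjusted p = 0.634), with a median of -0.14 and a mean of 0.03. Pmaip1 at 3.01 and Btg2 at -1.05 passed when adjusted over the list alone, 2 of 15, and 0 over all genes. In the BCL2 family 7 were higher and 6 lower (adjusted p = 0.568), and Pmaip1 was the 1 member past the threshold adjusted over the list alone. Of the chemokine receptors and homing genes 9 were higher and 4 lower (adjusted p = 0.237); without knockout replicate 3 the list was called higher (0.0366), in a range of 0.0366 to 0.632 at the preset correlation, and on all 6 arrays the adjusted p was 0.826 with an estimated correlation. The integrin genes Itgal at -1.18 and Itgb1 at -0.73, and the selectin ligand gene Selplg at 0.67, passed when adjusted over the list alone, 3 of 13. Fry's test for change in either direction passed 3 lists, p53 targets (adjusted p = 0.0402), chemokine receptors and homing genes (0.0387) and ERK feedback and immediate early genes (0.0387).

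Mitosis genes had 4 higher and 15 lower or with equal means (adjusted p = 0.262). The direction rested on single arrays: without knockout replicate 1 the list was called higher (adjusted p = 0.0459) and without knockout replicate 3 lower (0.000374), in a range of 0.000374 to 0.620 over 16 alternatives at the preset correlation. On all 6 arrays the adjusted p was 0.826 with an estimated correlation. DNA replication and G1/S genes had 9 higher and 11 lower or with equal means (adjusted p = 0.823), with a median of -0.01 and a mean of 0.01. Without knockout replicate 1 they were called higher (0.0210), in a range of 0.0210 to 0.987 (on all arrays, adjusted p = 0.945 with an estimated correlation). In 6 alternatives, among them without knockout replicate 3, the direction was lower. Heat shock and stress genes had 9 higher and 5 lower (adjusted p = 0.674), with Ddit4 at -0.81 and Atf4 at 0.48.

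Markers of other cell types were measured in the same arrays. Natural killer and cytotoxic genes had 7 higher and 1 lower (adjusted p = 0.102), with Gzma at 1.04. B cell markers had 10 higher and 2 lower (adjusted p = 0.104), with Blnk at 1.07, and monocyte and macrophage markers had 12 higher and 4 lower (adjusted p = 0.131), with Fcer1g at 0.62. Whether these 3 lists passed at the preset correlation depended on the arrays used; on all 6 arrays each had an adjusted p of 0.826 with an estimated correlation. The monocyte list was called higher with the filter at the 60th percentile (adjusted p = 0.0376), without wild-type replicate 1 (0.0340), wild-type replicate 2 (0.0148) or knockout replicate 3 (0.00127), and with wild-type replicates 1 and 2 averaged (0.0207), but turned to lower without wild-type replicate 3 (0.772) and without knockout replicate 1 (0.632), in a range of 0.00127 to 0.772. The natural killer list was called higher without wild-type replicate 1 (0.0162), without knockout replicate 3 (0.0105), with the replicate block (0.0321) and when averaged (0.0335), in a range of 0.0105 to 0.400. B cell markers were called higher without knockout replicate 3 (0.000722) and with the mean of probe sets (0.0481), in a range of 0.000722 to 0.400. Neutrophil and granulocyte precursor markers had 5 higher and 7 lower (adjusted p = 0.674), with a median of -0.03 and a mean of -0.11 but camera's direction higher. Erythroid markers had 2 higher and 9 lower (adjusted p = 0.610), platelet and megakaryocyte markers 5 higher and 3 lower (adjusted p = 0.634), and stroma and endothelium markers 3 higher and 2 lower (adjusted p = 0.823). No member of these 7 lists passed, over all genes or adjusted over the list alone.

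Genes next to Sh2b3 on chromosome 5 had 5 members higher and 12 lower (adjusted p = 0.104). Atxn2, the neighbour of Sh2b3, had a log2 fold change of -1.01, and passed when adjusted over the list alone, 1 of 17, and not over all genes. Its other probe sets had log2 fold changes of -1.28 and -1.42, and of -0.04 to -0.30 for the 3 others. Those 3 had group means of 1.99 to 3.93. The probe set at -1.42 had means of 3.99 in wild type and 2.57 in knockout. All 4 lie low on the scale, where little can be read. Brap had -0.50 and Ppp1cc -0.26. Ptpn11, given above as a regulator of cytokine signalling at -0.41, is also a member of this list. Whether its position, or that of the NOTCH1 target Dtx1, bears on their values was not tested. On chromosome 13, Serf1, Smn1, Naip2, Naip5 and Naip6 follow each other in the GRCm38.p6 gene order among tested genes, and Smn1 between them, chosen after its values were seen, had -0.28. The sex-linked genes had 2 higher and 2 lower (adjusted p = 0.674), with Xist at -0.60. Among lists that passed in no alternative, those of STAT5 targets, cytokine receptors, early thymocyte, stem and progenitor, neutrophil, erythroid, platelet, stroma and sex-linked genes turned direction in at least 1.

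**Figure D4:**
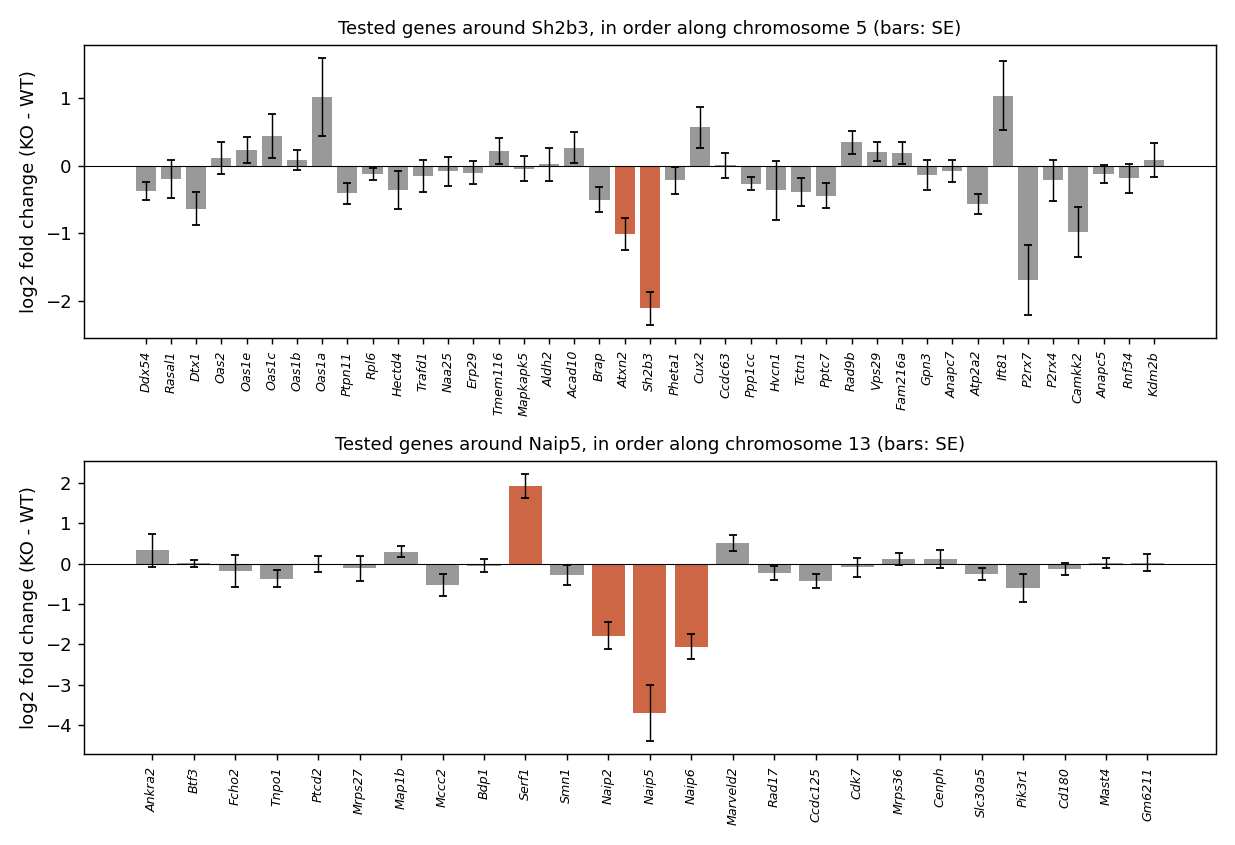
Log2 fold change, knockout minus wild type, of tested genes in their order along chromosomes 5 and 13, with bars for the standard error. Orange marks Sh2b3, Atxn2, Serf1, Naip2, Naip5 and Naip6, and all other genes are grey. Sh2b3 at -2.11 and its neighbour Atxn2 at -1.01 stand below 0, as do Naip2, Naip5 and Naip6, while Serf1 stands at 1.93. P2rx7, in grey and chosen after its values were seen, stands at -1.69, further below 0 than Atxn2.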

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

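Alternatives were chosen before the data were examined, except the fit with wild-type replicates 1 and 2 averaged, chosen after seeing the data. Sh2b3 was lower in knockout in all 16, with log2 fold changes of -2.27 to -1.07. On its more intense probe set the lowest wild-type value was 4.08 and the highest knockout value 2.29. Leaving out or averaging arrays could therefore not change its sign. The filters, the prior variance and the replicate block leave the log2 fold change unchanged, so the shared direction is a weak check. Leaving out 1 array gave -2.27 to -1.89, and the adjusted p of 0.0206 came without wild-type replicate 3, when the wild-type group is the pair of near-identical arrays. Genes higher numbered 0 to 20 and genes lower 0 to 31 with 1 array left out, and array weights gave 1 gene lower. The cause was not tested further. Same-numbered arrays did not vary together (correlations of -0.04, -0.05 and -0.05). No sign of pairing by number was seen, though this check alone cannot exclude it. With the replicate block 0 genes were higher and 0 lower, Sh2b3 stood at -2.11 with an adjusted p of 0.368, and 5 lists passed. Lists past the threshold numbered 2 with a constant prior variance, 0 with an estimated correlation, 0 with fry and 2 to 11 with 1 array left out, against 6.

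For 129 named genes, 2003 of 2040 values kept direction and side of the threshold. As no gene passed in the main comparison, no call could be lost. The filters and the prior variance leave a gene's log2 fold change unchanged, so direction could not change there. The count is thus a weak check. Another 15 values came to pass the threshold, 12 of them without wild-type replicate 3. The remaining 22, of 15 genes, changed sign, with adjusted p of at least 0.647 and cause not tested. Eif2s3y read -0.013 after the median shift and -0.092 with array weights, and Pecam1 -0.0065 with array weights. With the mean of probe sets, Hbb-b2 read 0.065, Kit 0.0067 and Mcl1 -0.12. The other changes of sign came with 1 array left out, where the values ran from -0.37 to 0.0067 for Car1, -0.083 to 0.022 for Cxcl12, -0.24 to 0.205 for Eif2s3y, -0.032 to 0.35 for Eomes, -0.32 to 0.56 for Gp1bb, -0.0033 to 0.25 for Hemgn, -0.44 to 0.17 for Itgb3, -0.085 to 0.21 for Pecam1, -0.13 to 0.79 for Pf4, -0.60 to 0.098 for Slc4a1, -0.207 to 0.053 for Sparc and -0.84 to 0.18 for Uty. Probe sets near 2 on the log2 scale are close to background, which limits what can be read for Kit, Cxcl12, Sparc and Eomes.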

Other observations

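Genes named in this paragraph were chosen after their values were seen. The T cell receptor transcripts differed between arrays within a group. Trbv13-2 read 8.41 and 8.40 on knockout arrays 2 and 3 and 2.05 to 3.27 on the others. The most intense Trgv4 probe set read 5.21 and 4.41 on wild-type arrays 1 and 2 and 7.37 to 10.76 on the others. Another Trgv4 probe set read 1.78 to 1.86 on all 3 wild-type arrays, and 6.10, 2.43 and 5.91 in knockout. Igha was highest on wild-type array 3, at 12.10, with 11.32 to 11.38 in knockout and 9.41 and 9.22 on wild-type arrays 1 and 2. Toward the other end of the gene window around Sh2b3 on chromosome 5, P2rx7 had a log2 fold change of -1.69, Camkk2 -0.98 and Atp2a2 -0.57, none past the threshold.

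Genes named in this paragraph for other blood cells were chosen after their values were seen. The granulocyte gene Mmp9 read 2.84 ± 0.15 in wild type and 3.13 ± 0.12 in knockout, near the bottom of the scale. The granulocyte gene S100a8 read 11.05 ± 0.09 in wild type and 11.18 ± 0.11 in knockout, and the erythroid gene Slc4a1 read 11.72 ± 0.17 and 11.44 ± 0.70. Xist read 6.83 to 8.11 and the Y-linked Eif2s3y 8.87 to 9.75, so that both were present on all 6 arrays.

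Of the tests below, those on the pair of similar arrays, the shared sequence of Naip genes, the share of plasma cells with its bootstrap interval, the neighbouring genes under other splits and the splits for gene counts were chosen after the results were seen. The fit with wild-type arrays 1 and 2 averaged was likewise added after the data were seen. Wild-type arrays 1 and 2 lay closer together than any other 2. Among genes with a mean above 5, 0.149% differed by more than 1 between them, against 4.43% for the next closest pair, which is what 1 tumour or 1 RNA extract measured on both arrays may give. The mean absolute difference over markers of other cell types was 0.214, against 0.484 for the next lowest pair. This value lay between the bounds set for 1 leukemic clone grown in 2 recipients, which stays open.

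The Naip genes and Serf1, neighbours on chromosome 13 that were picked for their small p, had values that did not overlap between groups, none past the threshold. A hypothesis is a chromosome segment of another strain carried with the knockout. Away from this cluster and from Sh2b3, 7 pairs of neighbouring genes had a p under 0.01, against a median of 2 in 10000 random gene orders (permutation p = 0.0112). For as many genes, the 4 splits that keep wild-type arrays 1 and 2 in 1 group, the real one among them, gave 6 to 7 pairs, and the 6 splits that part them gave 1 to 4. The count of 7 may therefore come from how that pair of arrays falls into groups. It leaves out the genes around Naip5 and Sh2b3, so it cannot decide whether a segment lies at either place. The hypothesis was not tested there and stays open. Probe sequence shared among Naip genes does not account for Serf1, which has a log2 fold change of 1.93 the other way, but stays open for the Naip genes alone.

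Immune and plasma cell lists stood higher in knockout. With wild-type arrays 1 and 2 averaged, in case they are 1 sample, 3 of the 3 lists of other cell types and interferon still passed at the preset correlation, and 5 of all 6 called lists, while the monocyte list (adjusted p = 0.0207) and the natural killer list (0.0335) came to pass. The bound set for double counting as the whole source of the 3 immune calls was that 0 of them stay. The bound set against it asked that all 6 calls stay, and the ERK feedback and immediate early list was lost (0.129). As other lists came to pass when averaged, calls need not fall when arrays are merged. The test therefore cannot exclude double counting, which stays open in whole or in part. On all 6 arrays, not averaged, each of the 6 called lists had an adjusted p of 0.826 with an estimated correlation. A higher share of plasma cells in knockout may also contribute. Over 28 immunoglobulin probe sets the median of the lowest knockout minus the highest wild-type value was -0.57, with 7 of them above 0. This met the bound set against it, but a 95% bootstrap interval over probe sets (-1.02 to -0.195) spanned that bound. The interval takes probe sets read on the same arrays as independent and does not measure the spread between samples. Per array, the median over these probe sets was 7.125, 6.645 and 5.2 on knockout arrays 1, 2 and 3. On wild-type arrays 1, 2 and 3 it was 5.065, 4.95 and 5.685. Many of the 28 probe sets lie near the bottom of the scale. The lowest knockout minus the highest wild-type value rests on single arrays, so it says little about the average share. The share of plasma cells stays open. Of 9 probe sets of Ighm, chosen after their values were seen, 5 were higher on every knockout array, while Igha was highest on a wild-type array. A change in the leukemic cells themselves was not tested.

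The 6 samples allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 0 genes past the threshold, and the highest of the others 16. With 0 in the real split this comparison decides nothing. At an unadjusted p under 0.05 the real split gave 981 genes and the highest other 973, so that 1 split, the real one, reached its count. The 4 splits that keep wild-type arrays 1 and 2 together gave 871 to 981 genes and the 6 that part them 178 to 745, so that the count went with this pair. For lists the real split gave 6 and the highest other 15, and 5 of the 10 splits gave at least as many. These list counts use the preset correlation.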
